A study of Rattus norvegicus with 13 samples.

How the data were processed

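RNA was extracted from the medial preoptic area (MPOA) of adolescent male SAS Sprague-Dawley rats and sequenced after standard Illumina library preparation, per the labels' protocols. The labels name 13 samples, of which 7 carried a scrambled short hairpin RNA (shRNA) and 6 an shRNA against Oprm1, each delivered by an adeno-associated virus. The label of 1 Oprm1 shRNA sample, number 6, calls it an outlier kept out of the analysis, which leaves 5 samples against 7. The labels do not state that each sample is a separate rat, so the p-values measure the spread between these samples. The labels give no batch, day or litter, and they do not say whether the libraries kept strand.

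The submitters' processing notes name bcl2fastq 2.20, STAR 2.5.3a, RSEM, edgeR 3.28.0 and the rat genome build Rnor_6.0. The annotation release, the filter on low counts, the dispersion setting and any covariates were not given in the sources used here. The data used here were the authors' deposited table of one edgeR comparison, Oprm1 shRNA against scrambled shRNA, with 14855 genes. For each gene the authors gave a log2 fold change, positive where the Oprm1 shRNA group was higher, and the log2 of the average CPM (read counts scaled by library size) over the libraries. The authors also deposited the likelihood ratio statistic (LR) of their fit, a score with no fixed range, and an unadjusted and a Benjamini-Hochberg adjusted p-value. The deposited p-values were those of a chi-square distribution with 1 degree of freedom at the deposited LR, checked on every gene. The authors' adjusted p-values imply 14859 tests, 4 more than the genes analysed here. The table does not name the libraries behind its fit, and the 7 and 5 samples are those the labels leave in.

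Values for single samples were not analysed here. The depth per sample is therefore unknown, no count test, leave-one-out fit or exchange of sample labels was run, and the spread between replicates enters only through the authors' LR. The planned test, a quasi-likelihood fit of counts, gave way to the case foreseen for a table of the authors' own comparison, in which the deposited fold changes and p-values are used as given. Adjusted p under 0.05 was the threshold. No genomic coordinates are printed, because the gene table at hand belongs to another assembly (GRCr8) than the authors' build.

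An implied standard error was computed for each gene as the absolute log2 fold change divided by the square root of the LR, and from it an approximate 95% interval of the fold change. This treats the LR as a squared standard normal value. It is poor for genes with reads in few libraries, whose fitted fold changes depend on the authors' prior count and are no bound on the true change. For such all-or-none genes only the fitted log2 value is given. RSEM divides reads among similar transcripts by an estimate, so genes with close paralogs or pseudogenes, such as Gapdh, Ube2b, the RT1 genes of the major histocompatibility complex (MHC), the hemoglobin genes and ribosomal protein genes, carry added uncertainty. Without a statement on strand, reads from overlapping or antisense genes cannot be told apart either.

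The gene lists, their tests and the rule for named genes were fixed before the data were examined. There were 17 pathway lists, 19 lists of cell type markers and 2 lists defined by symbol patterns. The 36 lists with at least 5 measured members were tested with limma's cameraPR on the signed square root of the LR, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 36 lists. The shift of a list is the mean signed square root of the LR of its members minus that of all other genes. An estimated correlation needs values per sample and could not be had, so no call below is backed by one. Members were also counted with their p-values adjusted over the list alone. As an alternative, the median log2 fold change of each list was set against 10000 random lists matched on abundance. The pattern for mitochondrially encoded genes matched no symbol, and 13 such genes were taken by the names the table uses, a list chosen after seeing the data. Of the lymphocyte markers 2 were measured, too few for the test.

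The genes named are the 8 opioid receptor and peptide genes, then in each direction up to 10 genes past the threshold with a gene symbol and an average of at least 1 CPM, by smallest p. Where fewer than 5 passed, the genes with the smallest unadjusted p fill the number to 5 and are given as values, not as changes. In each list the 3 members with the smallest p among those past the threshold are named, or, where none passes, the 2 with the smallest p. A list of whose direction nothing is said may go without names. The 1491 identifiers without a gene symbol are counted and not named. Some genes that the rule names are not reported here. Genes outside this rule were chosen after their values were seen and are marked so where they appear.

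Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used. The cameraPR step was tested on simulated data for this comparison, over 14855 genes and 50 simulations. With a shift of 0.9 planted, 93.4% of planted lists with at least 15 members were recovered, and 0.0556% of unchanged lists were called. In these simulations the genes were independent of one another, so the rates do not cover lists whose genes vary together. The planted 0.9 exceeds the observed shifts of interferon genes (0.63) and ribosomal protein genes (0.39), but not that of antigen-presentation genes (1.10). The random-list step, on the same 14855 genes, called 100% of 40 lists shifted by 2 on the log2 scale and 5% of unshifted lists at an unadjusted p under 0.05. Here fold changes were shuffled gene by gene among genes of like abundance, so correlated lists are not covered. The planted 2 exceeds the observed offsets of interferon (0.83), antigen-presentation (0.72) and ribosomal protein genes (0.14), so recovery at those sizes was not tested. Alternatives covered other thresholds, a fold minimum, other sets of genes for the adjustment, ranks, abundance minimums, the random lists and a higher preset correlation.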

Results

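Gene expression was measured by RNA sequencing in the MPOA, a hypothalamic region known for its part in sexual, parental and social behaviour, of adolescent male rats. On postnatal day 21 each rat received 0.5 uL per side of an adeno-associated virus of serotype 5 (AAV5) that carried GFP and either an shRNA against Oprm1, the gene of the mu opioid receptor, or a scrambled shRNA. Tissue was dissected from sections of 200 micron thickness between −0.24 and −0.72 mm from bregma. Of the 13 labelled samples, 7 were scrambled and 6 were Oprm1 shRNA, and 1 of the latter was left out by its label, so that 12 samples remained. The comparison asks which genes differ in this region between rats given the shRNA against Oprm1 and rats given the scrambled shRNA.

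The authors' deposited table held 14855 genes with a median abundance of 22.2 CPM. Depth per sample is unknown, and the precision of each fold change was read from the authors' LR. For genes of log2 average CPM between 2 and 4 in the authors' deposited table, the median implied standard error was 1.29 on the log2 scale, so that only differences beyond about 5.77-fold clear an approximate 95% interval. Between log2 CPM 4 and 6 this limit was 2.05-fold in the authors' deposited table. It was 1.42-fold between log2 CPM 6 and 8 and 1.24-fold above 8 in the authors' deposited table.

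The targeted gene, Oprm1 (ENSRNOG00000018191), had a log2 fold change of −0.58 in the authors' deposited table, at an average of 7.32 CPM. This is a fold of 0.670 with an approximate 95% interval from 0.0715 to 6.27 (the authors' p = 0.725, adjusted p = 0.9997). A reduction of Oprm1 transcripts was not detectable at this abundance, and the interval leaves room for a large one as well as for none. The level of the targeted gene therefore does not check the group labels in either direction.

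Among the other opioid genes, Penk, the enkephalin precursor, was the most abundant at 202 CPM and had a fold of 1.15 (interval 0.871 to 1.52) in the authors' deposited table. The kappa receptor gene Oprk1 had a fold of 0.669 (0.276 to 1.62), the nociceptin receptor gene Oprl1 a log2 fold change of 0.27, the dynorphin precursor gene Pdyn −0.45 and the nociceptin precursor gene Pnoc −0.26 in the authors' deposited table. The delta receptor gene Oprd1, at 0.865 CPM, had a fitted log2 value of −7.72 with an unadjusted p of 0.0471 in the authors' deposited table, and Pomc, at 0.693 CPM, had −1.62. Both lie at the floor of detection. Every one of these 8 genes had an adjusted p of 0.9997 in the authors' deposited table. As a list, 2 of the 8 were higher and 6 lower, with a median log2 fold change of −0.51 (cameraPR adjusted p = 0.627), and 0 passed adjusted over the list alone. The list's shift of −0.357 was −0.0868 among genes with log2 average CPM of at least 0, which leaves out Oprd1 and Pomc.

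**Figure D1:**
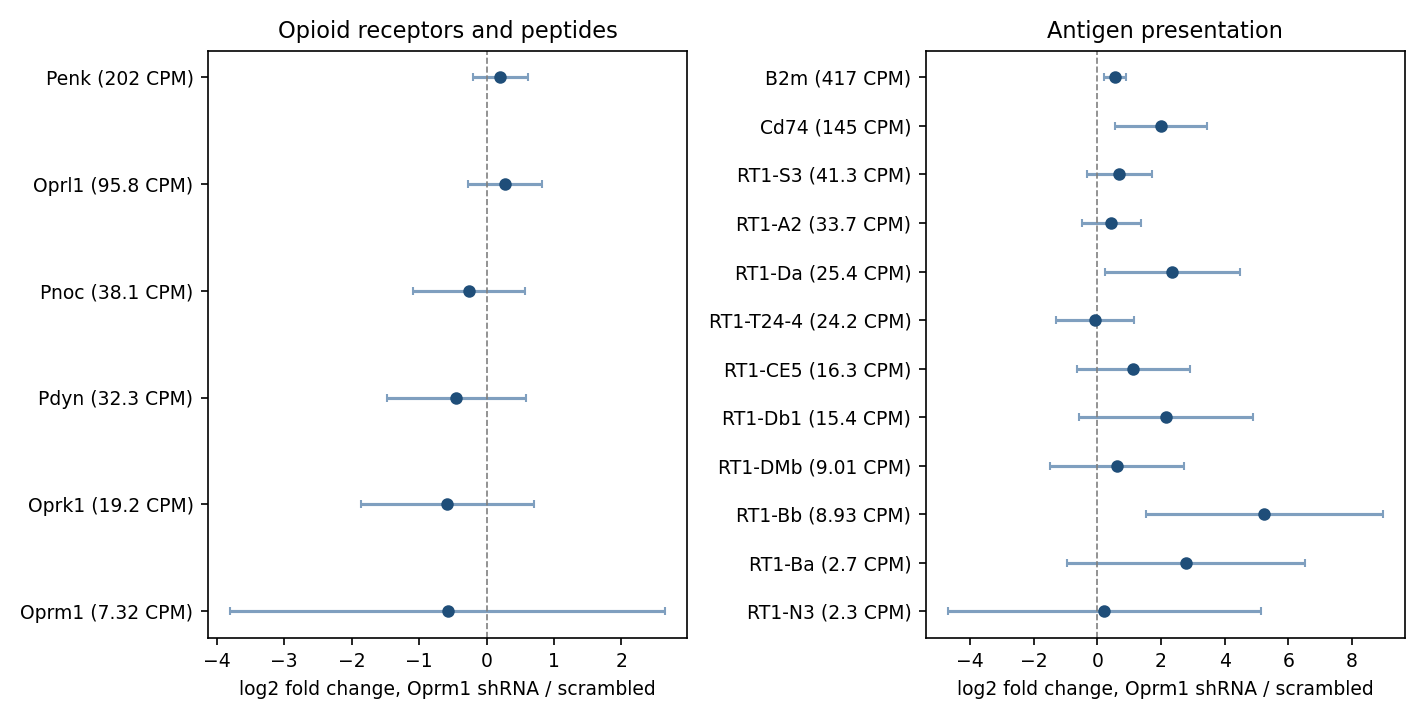
Log2 fold change of Oprm1 shRNA over scrambled shRNA (x axis) in the authors' deposited table for the opioid genes (left) and the antigen-presentation list (right) that averaged at least 2 CPM, with average CPM beside each symbol; points are fitted values and bars approximate 95% intervals from the implied standard errors. The interval of Oprm1 runs across 0 from −3.81 to 2.65, while those of B2m, Cd74, RT1-Bb and RT1-Da lie above 0 before any adjustment. The cut at 2 CPM leaves out RT1-A1 (−3.68) and RT1-CE10 (−2.51), lower, and Ciita, RT1-DMa and Nlrc5, higher. These were named after their values were seen.

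At an adjusted p under 0.05, 3 genes rose and 0 fell in the authors' deposited edgeR comparison of 14855 genes. Gapdh (ENSRNOG00000018630), a glycolytic enzyme widely used as a reference gene, rose 1.17-fold (interval 1.11 to 1.22) at 1690 CPM, with an adjusted p of 7.9e-06 in the authors' deposited table. Psap (ENSRNOG00000000571), the precursor of the lysosomal saposins, rose 1.19-fold (1.10 to 1.27) at 1830 CPM, with an adjusted p of 0.0166 in the authors' deposited table. Ube2b (ENSRNOG00000005064), a ubiquitin-conjugating enzyme, had a fitted log2 value of 12.19 at 14.5 CPM and an adjusted p of 0.00121 in the authors' deposited table. A value of that size comes from a gene with almost no reads in one group, so no fold is given for Ube2b.

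Of the genes that did not pass, Tubb4a, a tubulin of oligodendrocytes and neurons, had a log2 fold change of 0.09 and an adjusted p of 0.229 in the authors' deposited table. Impad1 (ENSRNOG00000027079) had a fitted value of 10.81 at 5.64 CPM and the same adjusted p there, while a further row of that symbol (ENSRNOG00000046647) had −0.21 at 323 CPM in the authors' deposited table. On the lower side stood Sparcl1, an astrocyte-secreted synaptogenic protein, at −0.23 with an adjusted p of 0.0572 in the authors' deposited table. Nexmif, a neurite extension factor, had −1.15 (adjusted p = 0.371) in the authors' deposited table. Nup214 and Aldh18a1 had fitted values of −9.71 and −11.32 at 3.14 and 9.31 CPM in the authors' deposited table, with adjusted p-values of 0.232 and 0.371.

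At an unadjusted p under 0.05 the authors' deposited table held 652 genes, 221 higher and 431 lower, against 743 expected by chance among 14855. Of the 652, 338 had a log2 average CPM under 2 in the authors' deposited table, where 2776 genes lie, while between 2 and 4 the share was 1.02% of 3541 genes. Gapdh, Psap, Tubb4a and Sparcl1 lie in a narrow band of abundance, from 1218 to 2435 CPM, in which the median implied standard error was 0.0561 on the log2 scale. It was 0.102 in the next lower band of equal width and 0.129 above it in the authors' deposited table. With the standard errors of the band raised to 0.102, an alternative chosen after seeing the data, Gapdh and Psap had adjusted p-values of 0.9997. The 1 call left was Ube2b. At 14.5 CPM it lies outside the band, so the reset did not test its all-or-none value.

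**Figure D2:**
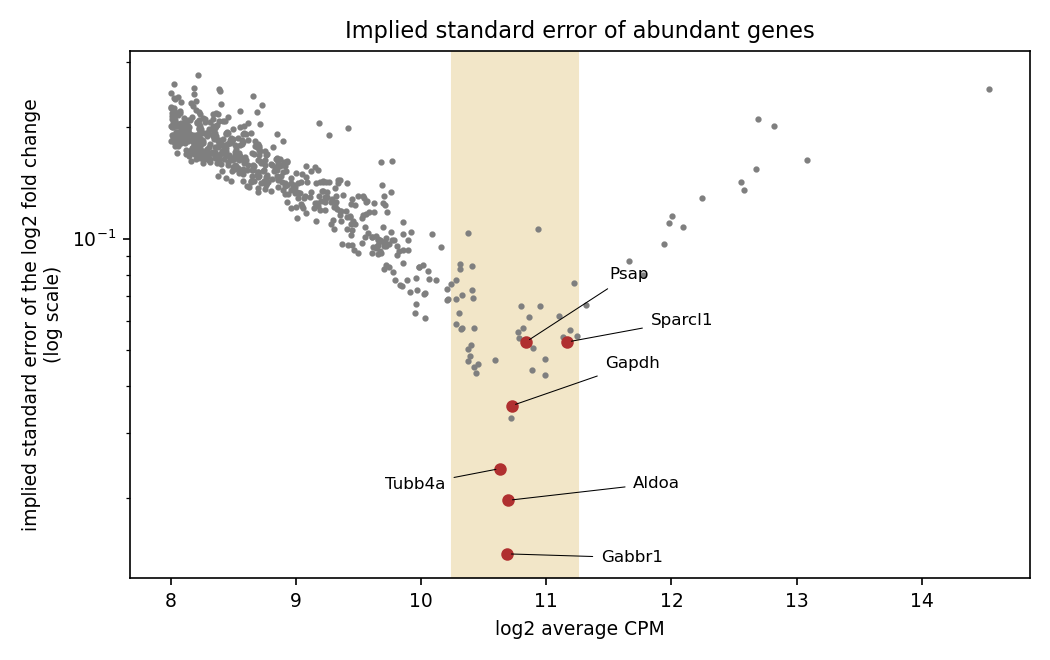
Implied standard error of the log2 fold change (y axis, log scale) against log2 average CPM (x axis) for the genes of the authors' deposited table with log2 CPM of at least 8, each point a gene. The shaded band runs from 1218 to 2435 CPM and holds 45 genes; the red points inside it are Gapdh at 0.0355, Psap, Sparcl1, Tubb4a, Gabbr1, with a standard error of 0.0142, and Aldoa, which was chosen after its values were seen.

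Genes of antigen presentation were higher with Oprm1 shRNA as a list. Of 17 measured members 14 were higher and 3 lower in the authors' deposited table, with a median log2 fold change of 0.69 and a shift of 1.10 (cameraPR adjusted p = 0.000117). Adjusted over the list alone 3 members passed, and over all genes 0. B2m, the light chain of MHC class I, was 1.48-fold higher (interval 1.16 to 1.88) at 417 CPM in the authors' deposited table, with a p adjusted over the list alone of 0.0233. Cd74, the invariant chain of MHC class II, was 3.99-fold higher (1.46 to 10.9) at 145 CPM in the authors' deposited table. The class II gene RT1-Bb had a log2 fold change of 5.25 at 8.93 CPM there, with a wide fold interval of 2.89 to 504. Cd74 and RT1-Bb both had a p adjusted over the list alone of 0.0399. RT1-Da, a class II gene chosen after its values were seen, had a log2 fold change of 2.36 and an unadjusted p of 0.0297 in the authors' deposited table. The call held in each alternative, including a preset correlation of 0.05 (adjusted p = 0.00669).

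Interferon-induced genes were also higher as a list, which shares no member with the antigen-presentation list. Of 33 measured members 25 were higher and 8 lower in the authors' deposited table, with a median log2 fold change of 0.80 and a shift of 0.63 (cameraPR adjusted p = 0.00832). Adjusted over the list alone 2 members passed, in opposite directions, and over all genes 0. Ifit1bl had a fitted log2 value of −8.77 at 1.68 CPM in the authors' deposited table (0.0387 over the list alone), close to the floor. Cxcl10, a chemokine chosen after its values were seen, had a log2 fold change of 2.91 and an unadjusted p of 0.0392 in the authors' deposited table. The authors gave values near 0 for Stat2 (−0.18), Ifi27 (0.25), Isg15 (0.19) and Irf7 (−0.02), chosen after their values were seen. Of these, only the interval of Stat2 lies below the list's median of 0.80. With a preset correlation of 0.05, chosen after seeing the data, the list's adjusted p was 0.226.

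Beside these 2 lists, markers of microglia and macrophages had a median log2 fold change of 0.09, with 9 of 16 higher (cameraPR adjusted p = 0.679). Their members with the smallest p were Trem2 at −2.64 and the complement gene C1qa at 0.31 in the authors' deposited table. Cytokine, complement and innate sensor genes had 14 of 23 higher and a median of 0.55 (adjusted p = 0.649 by cameraPR), led by Cxcl11 at a fitted −8.60 and C1s at 1.14 in the authors' deposited table. Against random lists matched on abundance, that median lay at percentile 99.7, with an adjusted p of 0.0522 for the authors' fold changes, so a higher level of this list is not excluded. Markers of reactive astrocytes had 7 of 11 higher (adjusted p = 0.513), with Cxcl10 and Gfap, at 0.37, of smallest p in the authors' deposited table. The 2 lymphocyte markers measured, Cd4 and Lck, had log2 fold changes of −1.89 and 0.40 in the authors' deposited table.

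Cytosolic ribosomal protein genes were the third list called. Of 81 members 50 were higher and 31 lower in the authors' deposited table, with a median log2 fold change of 0.13 and a shift of 0.39 (cameraPR adjusted p = 0.0437). No member passed over all genes or adjusted over the list alone, a count of 0 beside 4 at an unadjusted p under 0.05. Rpl9 was 1.40-fold higher (1.08 to 1.82) in the authors' deposited table, at an unadjusted p of 0.0104. The adjusted p was 0.0707 with ranks in place of the statistic and 0.581 with a preset correlation of 0.05. The 13 mitochondrially encoded genes, which made up 6.83% of the summed average CPM, had 11 lower and 2 higher with a median of −0.06 in the authors' deposited table (unadjusted cameraPR p = 0.0554).

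Immediate early genes, which report recent neuronal activity, were not called as a list (adjusted p = 0.649). Egr1 was the single member that passed adjusted over the list alone (0.0156), with a fold of 0.271 (0.126 to 0.583) at 25.9 CPM in the authors' deposited table, and over all genes it did not pass. Nr4a1 had a log2 fold change of −2.34 with an unadjusted p of 0.0424 in the authors' deposited table. The list's median of 0.23, with 12 of 19 higher, and its mean shift of −0.17 differ in sign.

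No list of neurotransmitter or hormone genes was called. Neuropeptides of the preoptic area and hypothalamus and their receptors had 24 higher and 24 lower (adjusted p = 0.798), and the neurotensin receptor gene Ntsr1 at 1.81 and the vasopressin gene Avp at −2.04 had the smallest p in the authors' deposited table. GABA genes had 14 of 22 lower with a median of −0.07 (adjusted p = 0.627), and Gabbr1 at −0.04 and Gabra2 at 0.55 led the list in the authors' deposited table. Gabbr1 lies in the band of small standard errors. Glutamate genes had 18 of 27 lower with a median of −0.19 (adjusted p = 0.627), led by Grik3 at −0.82 and Gria2 at −0.20 in the authors' deposited table. Dopamine genes had 7 of 11 lower (adjusted p = 0.649), with a fitted −8.10 for Drd5 at 1.10 CPM and −1.11 for Slc18a2, the vesicular monoamine transporter gene, in the authors' deposited table. Receptors and enzymes of sex steroids, corticosteroids and prolactin had 8 of 13 lower (adjusted p = 0.627), led by Hsd17b4 at −0.56 and the progesterone receptor gene Pgr at −0.99 in the authors' deposited table.

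Genes with high-confidence links to autism had 19 of 27 lower with a median of −0.16 (adjusted p = 0.625), and Ube3a, at −0.61, was among the members with the smallest p in the authors' deposited table. Genes of G protein signalling downstream of opioid receptors had 18 of 27 lower with a median of −0.08 (adjusted p = 0.627), led by Gnaz at −0.59 and Kcnj3, a GIRK channel gene, at −1.60 in the authors' deposited table. The other pathway lists were serotonin and noradrenaline genes (18 measured, adjusted p = 0.649), endocannabinoid genes (8 measured, 0.880), synaptic vesicle genes (20 measured, 0.875), unfolded protein and heat shock genes (21 measured, 0.627) and the microRNA and shRNA machinery (13 measured, 0.880), all by cameraPR. The median and the mean shift differed in sign for the neuropeptide, endocannabinoid, cortical and oligodendrocyte precursor lists.

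No list of cell type markers was called, with a smallest adjusted p of 0.257, for astrocytes. Astrocyte markers had 10 of 13 lower with a median of −0.09, and the glutamate transporter gene Slc1a2 had a log2 fold change of −1.47 beside 0.37 for the filament gene Gfap in the authors' deposited table, the former with an unadjusted p of 0.0275. Restricted to log2 average CPM of at least 4, a filter chosen after seeing the data, the astrocyte list had a shift of −0.89 and a cameraPR adjusted p of 0.0167. In the other alternatives it did not pass, with an adjusted p of 0.581 at a preset correlation of 0.05 and 0.591 against random lists matched on abundance. Markers of cholinergic neurons were higher in 8 of 8 genes with a median of 0.71 (adjusted p = 0.298), among them Isl1 at 0.93 and Chat, the acetylcholine-synthesizing enzyme, at 1.27 in the authors' deposited table. Markers of preoptic and anterior hypothalamic neurons had 10 of 12 higher with a median of 0.51 (adjusted p = 0.513), led by Otp at 3.09 and Hmx2 at 1.84, each under 4 CPM in the authors' deposited table.

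For the pan-neuronal markers 6 of 12 were higher (adjusted p = 0.627), with Map2 at −0.15 and Syt1 at −0.18 in the authors' deposited table, and Map2 too lies in the band of small standard errors. Myelinating oligodendrocytes had 11 of 13 markers lower with a median of −0.07 (adjusted p = 0.649), led by Ugt8 at −0.26 in the authors' deposited table. Markers of tissue next to the dissected area gave adjusted p-values of 0.875 for striatum and septum (12 measured), 0.649 for cortex and hippocampus (6 measured), 0.725 for thalamus (7 measured) and 0.627 for other hypothalamic neurons (5 measured). By cameraPR the adjusted p was 0.627 for oligodendrocyte precursors (9 measured), 0.760 for endothelium (9 measured), 0.627 for mural cells (9 measured) and 0.513 for meningeal fibroblasts (11 measured). It was 0.646 for ependyma (11 measured), 0.627 for choroid plexus (5 measured) and 0.649 for red blood cells (6 measured). In each of these marker lists 0 members passed over all genes or adjusted over the list alone.

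**Figure D3:**
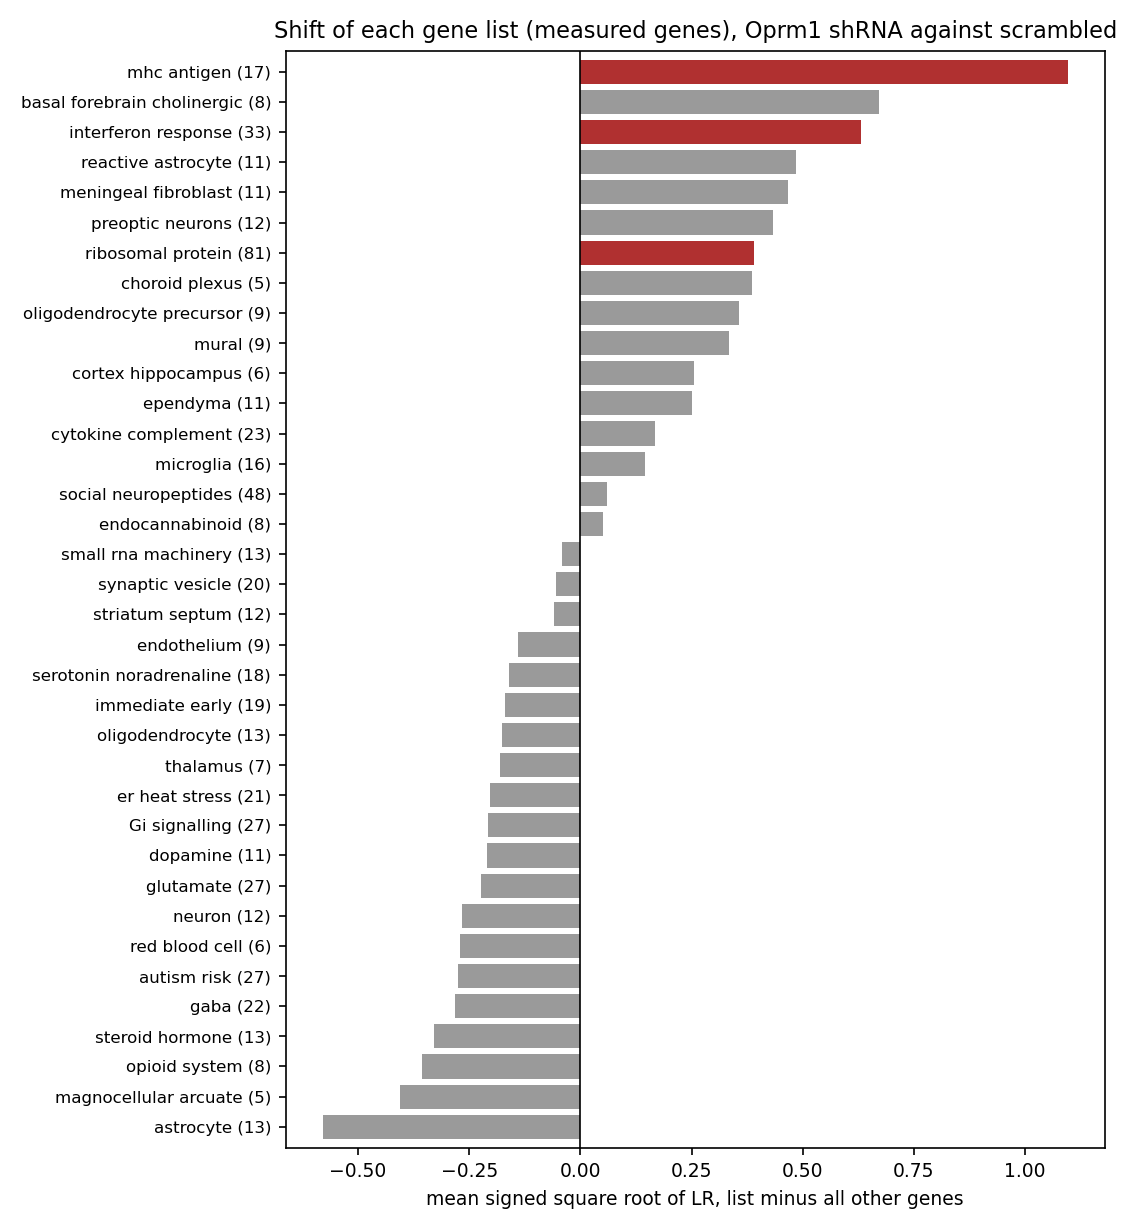
Shift of each of the 36 tested gene lists (x axis, mean signed square root of the authors' LR in the list minus that in all other genes), with the number of measured genes in brackets and the lists in order of shift on the y axis. Red bars are the 3 lists with a cameraPR adjusted p under 0.05, antigen presentation at 1.10, interferon response at 0.63 and ribosomal proteins at 0.39; grey bars are the 33 others, down to −0.58 for astrocyte markers.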

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

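The preset correlation of 0.05, the minimum of log2 CPM 4 and the reset of standard errors were chosen after the results were seen, and the other alternatives before the data were examined. The count of 3 genes in the authors' deposited table was 4 at an adjusted p under 0.1 and 2 under 0.01, and 3 with the adjustment redone over the 14855 genes or over those with log2 CPM of at least 0. It was 652 at an unadjusted p under 0.05. It was 1 with a minimum of 1.5-fold, which by construction removes Gapdh and Psap, and 1 with the standard errors of abundant genes reset, which raises theirs. For Oprm1 the log2 value is the same by construction where the adjustment was redone.

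The count of 3 lists was 2 with ranks, 3 at log2 CPM of at least 0 or against random lists, and 4 at log2 CPM of at least 4. It was 1, antigen presentation, with a preset correlation of 0.05, which widens the null by construction. Of 168 alternative values for single lists, 158 kept direction and side of the threshold, 3 lost and 1 gained the call, and 6 reversed, none of them past the threshold. Against random lists, which compare medians where the shift compares means, endocannabinoid genes (−0.0545), immediate early genes (0.29) and oligodendrocyte precursors (−0.0175) reversed, and the median and mean of these lists differ in sign. Dopamine at log2 CPM of at least 4 (0.37) and red blood cells at log2 CPM of at least 0 (0.0129) and against random lists (0.00025) also reversed, and the cause was not tested.

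No paired analysis was possible because the authors' table holds no values per sample, although both groups share 3 numbers among the samples kept. For the same reason DESeq2, other normalizations and count filters, pseudocounts, leaving out each replicate, putting back number 6, other splits of the samples and an estimated correlation were not run. Between log2 CPM 2 and 4, precision limits single genes to differences beyond about 5.77-fold. The approximate limit was 41.1-fold from log2 CPM 0 to 2 and 130-fold under 0.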

Other observations

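All tests in this part were chosen after the results they bear on were seen.

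In the antigen-presentation list, split after the values were seen, all 8 class II genes and regulators, Cd74, Ciita, RT1-Ba, RT1-Bb, RT1-Da, RT1-Db1, RT1-DMa and RT1-DMb, were higher in the authors' deposited table (cameraPR p = 3.3e-07), against 6 of the other 9 genes (p = 0.0663). The difference between these groups was not tested, and the smallest p of the list belongs to B2m, of class I. Irf8, a transcription factor of microglia and antigen-presenting cells that no list held, was 2.80-fold higher (1.32 to 5.95) at 26.2 CPM with an unadjusted p of 0.00749 in the authors' deposited table. On the lower side, Ptprz1, a receptor phosphatase of astrocytes and oligodendrocyte precursors that no list held, had a fold of 0.726 (0.596 to 0.886) at 347 CPM with an unadjusted p of 0.00157 in the authors' deposited table. Neither passed the adjustment over all genes.

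Antigen-presentation and interferon genes were higher together, as a union of 50 genes with 39 higher. More microglia in the tissue would raise their markers alike. The antigen-presentation list had a mean signed statistic of 1.03 against 0.0837 for the microglial markers (permutation test over genes, which are not independent, p = 0.00828). Their median log2 fold changes were 0.69 and 0.09. The antigen-presentation list had already been called on this statistic, which also grows with a gene's precision, so that p cannot exclude more microglia. Irf8, given above, was higher before adjustment. By abundance the first 3 listed microglial markers were Csf1r, with a log2 fold change of −0.08 (−0.59 to 0.43), C1qa, with 0.31 (−0.40 to 1.02), and Ctss, with −0.01 (−0.61 to 0.58), in the authors' deposited table. Of these, the interval of C1qa includes the antigen list's median of 0.69. Differences in MHC haplotype between the rats could move the RT1 genes through mapping but not the 30 interferon genes outside that region. Of those 30, 23 were higher (cameraPR on the authors' statistics, unadjusted p = 0.000697, and 0.0138 with a preset correlation of 0.05). At that preset the whole interferon list was not called (cameraPR adjusted p = 0.226). These 30 genes are most of a list already called on the same statistics, so their p-values add no independent support. For the 13 RT1 genes, 10 of them higher (cameraPR on the authors' statistics, p = 0.00101), haplotype and regulation cannot be told apart without genotypes. The 4 other members of that list, B2m, Cd74, Ciita and Nlrc5, were all higher as well, with a mean signed statistic of 1.76. That mean rests mainly on B2m and Cd74. Ciita and Nlrc5 averaged 1.39 and 1.25 CPM, with the authors' unadjusted p-values of 0.321 and 0.867. The shift does not rest on genes with few reads alone. Of the 15 genes with log2 CPM of at least 4, 13 were higher (cameraPR on the authors' statistics, p = 3.62e-08, and 6.38e-06 with a preset correlation of 0.05). Both lists had already been called on the same statistics, so this test adds no independent support. More microglia, and haplotype for the RT1 genes, are thus not excluded. A further candidate, not tested, is an interferon-like response that differs between the groups. It could come from the targeting of Oprm1, whose reduction was not detectable, the hairpin sequence or the virus preparation. It could also come from 1 or a few rats or a small number of infiltrating cells. Values per sample would be needed to test these.

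Small p-values gathered among abundant genes. In the band from 1218 to 2435 CPM, whose limits were drawn after these p-values were seen, 11 of 45 genes had an unadjusted p under 0.01, against 0 of 127 in the next lower band and 0 of 15 above. The standard error there was 1.81 times smaller, while the median absolute log2 fold change was 1.18 times that of the lower band (bootstrap 95% interval 0.817 to 1.70). Fold changes that had shrunk with the standard error would give 0.552, below that interval, so standard errors set low by the variance estimate may account for the calls of Gapdh and Psap. Correct standard errors with larger fold changes in this abundance band, up to the bound of 1.70, cannot be told apart from this without values per sample, and no biological explanation was tested.

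Very large fold changes leaned to the lower side. Of 483 genes beyond 5 on the log2 scale in the authors' deposited table, 401 were lower and 82 higher with Oprm1 shRNA, a ratio of 4.89 (exact 95% interval 3.85 to 6.28), and 469 of them lay under log2 CPM 2. The 14 at log2 CPM of 2 or more showed no such lean, with 7 higher and 7 lower. With 7 libraries against 5, a gene detected at random in a set number of libraries is absent from the smaller group more often, by ratios of 1.4, 2.1, 3.5, 7 and 21 for genes in 1 to 5 libraries. The observed ratio lies within that wide range, so patchy detection with unequal group sizes may contribute. The ratio was however 7.03 at log2 CPM under 0 and 3.86 from 0 to 2 (Fisher's exact test p = 0.0218), where genes seen in fewer libraries would give the smaller ratio. Without the number of libraries per gene, patchy detection and lower expression cannot be told apart.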
